A study of Mus musculus with 4 samples.

How the data were processed

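Liver RNA from female CD-1 mice was measured on 4 Agilent 2-colour mouse 44k expression arrays. Per the labels' protocols, RNA was extracted with Trizol, amplified in 1 round as aminoallyl antisense RNA and coupled to Alexa 555 or Alexa 647, and each array received 1 pool from Cux2 siRNA-treated mice and 1 pool from mice given a non-specific siRNA. The samples fall into day 5 (2 arrays) and day 8 (2 arrays), with the dyes exchanged between replicate 1 and replicate 2 of each day. The direction of every ratio was taken from the dyes in the labels. Each treated pool was made from mice of its own, whereas the 2 control pools recur, and the labels leave open which of them each array carried. Pools stand in for single animals, so the p-values measure the spread between pools, dye effects included.

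The scanner files were written by Agilent Feature Extraction 10.7.1.1, per the file headers. The deposited intensity values used here are the median pixel brightness of each spot and of its local background in each channel, as scanned. The design written beforehand had named mean signals; the scanner tables used here hold median spot signals, and these were taken in their place. The deposited processed intensity values are background-subtracted, detrended and dye-normalized by the scanner software, per the file headers, and served as an alternative. The authors' value table of the whole series holds log10 ratios. Set against the scanner's own log10 ratio per feature, its values were equal within 1e-05 for all 45018 features on every array once the sign was turned on the 2 arrays with the treated pool in Alexa 555, so its direction is treated over control on all 4 columns. Each column had a median of 0. The scanner's p-value of each spot's log ratio, deposited beside it, entered no test. The build named for the array design in the file headers is not that of the gene table used here, so no coordinates are given. Whether arrays were left out before deposit is not given in the sources used here.

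Medians of the spot signals lay between 381.5 and 471.5, over background medians of 306 to 342. Between 99 and 204 spots per array bore an outlier mark and were left out, and 0 were saturated. The slope of observed on designed log ratios of the spike-in controls was 0.908 to 0.923, so ratios were slightly compressed. The number of arrays limits the precision: the fit had 2 residual degrees of freedom and gained 2.78 from the prior.

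Values were computed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, log ratios were normalized within each array by loess with the 1639 control spots at weight 0, control spots were removed and the 43379 other spots averaged per probe. Probes were named through their RefSeq accession in a table of GRCm38.p6 genes: 23374 of 41174 probes (56.8%) matched, and 17800 were unnamed here and kept the accession of the file. A probe was kept when it was well above background in at least 2 of the 8 channel readings, which left 31757. Where a gene had several kept probes, as 5368 genes did, the one with the highest mean intensity stood for it. A gene with a treated or control channel below background throughout has only a bound there, and no gene named with a value is of this kind. One lmFit and eBayes fit over the 4 oriented arrays estimated day 5, day 8, their mean and their difference, sharing 1 spread between arrays. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 25091 genes tested.

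The design, the alternatives and 26 gene lists with 550 members, of which 508 matched a gene tested here, were set before the data were examined. The lists came from general knowledge of mouse liver and include markers of macrophages, neutrophils, lymphocytes, endothelium, stellate cells, bile ducts, red cells and exocrine pancreas. Cux2 is in none of them, and some genes are in more than 1 list (Alas2, for example, in the male-biased and the erythroid list). Each list was tested against all other genes by limma's camera with a preset correlation of 0.01 and adjusted over the 26 lists of a contrast. Repeated with a correlation estimated per list, camera called none. That version refers each test to the 2 residual degrees of freedom and so has little power. The estimated correlations were also far above 0.01 for some lists: 0.993 for pancreas, 0.504 for macrophage, 0.443 for acute phase and 0.244 for interferon genes. For such lists the p-values with the preset correlation may be too small. For heat shock genes the estimate was -0.038. The genes named are Cux2, and for day 5, day 8 and both days the 12 largest rises and the 12 largest falls among genes past the threshold that went the same way on each array of the contrast and have a gene symbol that is not a clone, accession or predicted-gene name. For the difference between days they are the 4 largest each way, as values. As no gene passed there, these had to differ at least 1.5-fold the same way in both replicates. From each list up to 4 members with the smallest p in a contrast are given with values. Others are named only as passing or not. Exceptions are genes named by the rule above, the haemoglobin genes and genes taken up after the results had been seen.

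The steps were tested on simulated spots for 25091 genes with 200 changed. Those 200 were drawn from genes outside the lists that were well above background in all 8 readings. The shares recovered therefore do not cover the dimmer genes among those tested. At day 5 the fit recovered 2.99%, 49.3% and 86.4% of genes changed by 0.5, 1 and 2 on the log2 scale, at day 8 2.99%, 53.7% and 84.8%, and over both days 11.9%, 82.1% and 93.9%, with 67, 67 and 66 genes of each size and at most 2 false calls. Median estimates were 0.748 to 0.905 of the true value, so changes are understated. Camera over both days called the 1 list of 26 that had been shifted. The simulated noise was independent between genes and between arrays. The false calls therefore say nothing about lists whose genes move together or about shared control pools.

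Replicate numbers are shared between the days, and each number is also a dye orientation. Deviations of the same-numbered arrays from their day's mean correlated at 0.5 across genes. The number may also follow the control pool, which the labels do not give per array. A term for it would then take the spread between control pools out of the error. Since the labels tie the number to the dye, the fit with the number as a term is given beside the counts it moves. The alternatives were no background subtraction, processed signals without loess, the authors' log10 table, median centring, Aquantile scaling, no filter on dim probes, a filter needing all 8 readings, eBayes with trend and robust estimation, the mean of all probes of a gene, an adjusted p of 0.1, a 1.5-fold minimum, the replicate term, and leaving out each array in turn. A day left with 1 array borrows its spread from the other day.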

Results

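The livers of female CD-1 mice, an outbred laboratory stock, were profiled after Cux2 had been knocked down with small interfering RNA (siRNA). Cux2 encodes a homeobox transcription factor whose expression in mouse liver is strongly female-biased, and the stated purpose was to find the genes that change when it is depleted. All mice were 8 weeks old. Each of 4 arrays compared RNA pooled from mice given Cux2 siRNA with RNA pooled from mice given a non-specific siRNA. At day 5 after treatment the treated pools held 3 mice (replicate 1) and 2 mice (replicate 2), and at day 8 each held 2 mice. The 13 control mice formed 2 pools of 6 or 7, according to the series description, while the sample descriptions give 6 control mice for every array. The labels do not say when the control mice were killed, nor which control pool was on which array. On both days the treated pool carried Alexa 647 in replicate 1 and Alexa 555 in replicate 2, so that replicate number and dye orientation coincide. The arrays came from 1 slide and 1 scan. Each had 41174 probes, of which 71.1% to 74.5% were well above background in a given channel, and no spot was saturated. The tests covered 25091 genes, 14063 of them with a gene symbol. Every ratio is on the log2 scale, Cux2 siRNA over non-specific siRNA. Standard errors (SE) come from 1 limma fit over the 4 arrays, with 2 arrays per day, and adjusted p-values from that fit by the Benjamini-Hochberg method.

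Cux2 was lower in the treated pool on every array, with log2 ratios of -1.91 and -1.70 at day 5 and of -1.07 and -1.20 at day 8. Its mean fell by 1.81 at day 5 (SE 0.09, adjusted p = 0.00299, limma), which left 28.6% of the control level. At day 8 it fell by 1.13 (SE 0.09, adjusted p = 0.00702), which left 45.6%. Over both days Cux2 averaged -1.47 (SE 0.06, adjusted p = 0.000913). The day 8 ratio lay 0.67 above the day 5 ratio (SE 0.12, unadjusted p = 0.0031), a difference that did not pass after adjustment over all genes (adjusted p = 1.00). A single probe measured Cux2. With median centring in place of loess the call was lost at day 5 (-1.82, adjusted p = 0.129) and at day 8 (-1.13, adjusted p = 0.277), and without day 8 replicate 2 it was lost at day 8 (-1.07, adjusted p = 0.0659).

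At day 5 the largest falls among named genes that passed were in genes induced by interferon and in genes of the acute phase response, and the largest rises were in Nat8 and its relative Nat8f5, which belong to a family of N-acetyltransferases of conjugated cysteine and lysine. Ifit1, an interferon-induced RNA-binding protein, fell by 4.52 (SE 0.12, adjusted p = 0.00181, 22.9-fold lower). The interferon-inducible GTPases Tgtp1 (-4.46), Gbp6 (-4.18), Gbp3 (-4.16), Gbp8 (-4.11) and Igtp (-3.86) fell with it, as did Ifi44 (-4.06) and Cxcl10 (-3.81), a chemokine that draws lymphocytes. Among acute phase products, the serum amyloids Saa1 (-4.30) and Saa3 (-3.76) and the iron-scavenging lipocalin Lcn2 (-4.02) fell. Reg2, a secreted protein made in quantity by pancreatic acinar cells, fell by 3.85. Nat8f5 rose by 3.96 (SE 0.21, adjusted p = 0.00391, 15.6-fold) and Nat8 by 3.82 (SE 0.10, adjusted p = 0.00181, 14.2-fold). Rises followed in Phlda2, an imprinted growth regulator (2.89), Gdpd3, a glycerophosphodiester phosphodiesterase (2.61), Npb, the precursor of neuropeptide B (2.47), and Acot1, an acyl-CoA thioesterase (2.25). The NADPH oxidase Nox4 rose by 2.20, the carboxylesterases Ces1e, Ces2b and Ces2c by 2.17, 1.92 and 1.86, the vesicular glutamate transporter Slc17a8 by 2.17 and the arachidonic acid epoxygenase Cyp2c23 by 1.85. In all, 4216 of 25091 genes passed at day 5, of which 1851 rose and 2365 fell. With the replicate number as a term in the fit 8238 passed (3832 rose, 4406 fell). That number is also the dye orientation and may follow the control pool, whose spread the term would then take out. Within 1 dye orientation each day had 1 array and no test. The count fell to 5 with median centring (1 rose, 4 fell), to 2004 with the scanner's processed signals, to 915 without day 5 replicate 1 and to 246 without day 5 replicate 2. Leaving out day 5 replicate 2 ended the calls of Gdpd3 (adjusted p = 0.0531), Ces2c (0.062), Cyp2c23 (0.0806), Gbp6 (0.0663), Cxcl10 (0.0687), Igtp (0.0907), Saa1 (0.0987), Saa3 (0.103), Reg2 (0.156) and Gbp8 (0.159), and leaving out day 5 replicate 1 those of Reg2 and Gbp8 (both 0.0507).

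Of 26 gene lists fixed before the data were examined, 12 differed from the other genes at day 5 by limma's camera test, 9 downwards and 3 upwards, and none did with an estimated correlation between genes (smallest adjusted p = 0.522 with an estimated correlation). Interferon response genes fell in 28 of 31 cases (29 adjusted over the list alone; camera adjusted p = 1.37e-23), for example Ifit2 (-2.83) and Ifit3 (-3.05), which like Ifit1 bind foreign RNA. Cell cycle genes fell in 26 of 29 (26 over the list alone; adjusted p = 2.37e-17), among them Stmn1, which regulates microtubules (-1.50), Cdc20, an activator of the anaphase-promoting complex (-1.49), and Mcm6, part of the replicative helicase (-1.71). Acute phase genes fell in 20 of 30 (22 over the list alone; adjusted p = 1.58e-11), including the protease inhibitor A2m (-3.06) and the orosomucoid Orm3 (-3.09). Markers of other cell types were lower beside them. Kupffer cell and macrophage markers fell in 8 of 18 (15 over the list alone; adjusted p = 3.53e-07), neutrophil markers in 5 of 11 (6 over the list alone; adjusted p = 0.000728), stellate cell and fibroblast markers in 7 of 16 with 1 rise (10 and 4 over the list alone; adjusted p = 0.0106) and lymphocyte markers in 4 of 16 (5 over the list alone; adjusted p = 0.0489). The 12 exocrine pancreas markers had a median of -3.10 (camera adjusted p = 0.000482), while none passed as a single gene over all genes tested and 10 did over the list alone. Heat shock genes rose in 9 of 15 with 1 fall (11 and 1 over the list alone; adjusted p = 1e-06), genes of the xenobiotic receptors CAR and PXR in 12 of 26 (16 over the list alone; adjusted p = 1.31e-06) and genes of fatty acid and triglyceride synthesis in 6 of 20 (6 over the list alone; adjusted p = 0.0435). With an estimated correlation the adjusted p was 0.522 for the interferon, cell cycle and heat shock lists, 0.527 for the xenobiotic, neutrophil and fatty acid lists, 0.56 for the acute phase and macrophage lists and 0.589 for the pancreas, stellate cell and lymphocyte lists. The fatty acid call was lost without day 5 replicate 1 (adjusted p = 0.0984), with the processed signals or the authors' log10 values (both 0.104) and without background subtraction (0.0501). The lymphocyte call was lost without day 5 replicate 1 (0.0793), without day 5 replicate 2 (0.075), with the replicate number as a term (0.0599), the processed signals (0.056), the authors' values (0.0564) or the mean of all probes (0.0511), and without background subtraction (0.0501).

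Among named genes that passed at day 8, interferon-induced and acute phase genes again had the largest falls and Nat8 had the largest rise. Ifit1 fell by 4.99 (SE 0.12, adjusted p = 0.00155, 31.8-fold lower), and Gbp3 (-4.47), Gbp6 (-4.46), Tgtp1 (-4.44), Ifi44 (-4.29), Igtp (-4.27) and the chemokine Cxcl9 (-4.00) fell beside it. The acute phase genes Saa1 (-4.49), Lcn2 (-4.28), Orm2, an orosomucoid (-4.01), and Saa3 (-3.94) fell, as did the metal-binding metallothionein Mt2 (-4.33). Nat8 rose by 3.66 (SE 0.10, adjusted p = 0.00155, 12.6-fold) and Nat8f5 by 2.97 (SE 0.21, adjusted p = 0.00637). Gdpd3 (2.42), Slc17a8 (2.16), Acot1 (2.14), the neurotrophin receptor Ntrk2 (2.02), Phlda2 (1.99), Npb (1.98), Ces1e (1.95), the transmembrane channel-like gene Tmc7 (1.79), the collectin Colec10 (1.73) and Pnpla3, a lipid droplet enzyme (1.73), also rose. In all, 3595 genes passed, of which 1574 rose and 2021 fell. With the replicate number as a term 7453 passed (3525 rose, 3928 fell). The count fell to 3 with median centring (0 rose, 3 fell; unadjusted, 7847 genes had p under 0.05 in the limma fit with loess), to 1475 with the processed signals, to 757 without day 8 replicate 1 and to 137 without day 8 replicate 2. Leaving out day 8 replicate 2 ended the calls of Colec10 (adjusted p = 0.0512), Gbp6 (0.0538), Npb (0.0695), Gdpd3 (0.0716), Saa1 (0.0803), Igtp (0.0828), Saa3 (0.0893) and Ntrk2 (0.119).

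At day 8 camera called 10 of the 26 lists, 6 downwards and 4 upwards, and again none with an estimated correlation. Interferon response genes fell in 28 of 31 (29 over the list alone; adjusted p = 6.62e-26), cell cycle genes in 25 of 29 (26 over the list alone; adjusted p = 1.84e-16) and acute phase genes in 21 of 30 (24 over the list alone; adjusted p = 2.79e-13). The ribonucleotide reductase subunit Rrm2 (-1.54), which makes DNA precursors, and the spindle protein Nusap1 (-1.30) were examples from the cell cycle. Lower with these groups were the macrophage markers (7 of 18 fell, 15 over the list alone; adjusted p = 8.95e-07), the neutrophil markers (4 of 11, 7 over the list alone; adjusted p = 0.00197) and the stellate cell markers (7 of 16 fell and 2 rose, the same over the list alone; adjusted p = 0.0358). Genes of CAR and PXR rose in 13 of 26 (17 over the list alone; adjusted p = 3.08e-08), heat shock genes in 8 of 15 with 1 fall (12 and 1 over the list alone; adjusted p = 8.54e-06) and genes of cholesterol synthesis and uptake in 4 of 24 (5 over the list alone; adjusted p = 0.00343). The circadian clock list moved up (6 rose and 3 fell of 19; 9 and 3 over the list alone; adjusted p = 0.0119). With an estimated correlation the adjusted p was 0.459 for the interferon, cell cycle, xenobiotic, heat shock, neutrophil, cholesterol and clock lists, 0.475 for the acute phase list, 0.543 for the macrophage list and 0.696 for the stellate cell list, whose call was also lost without day 8 replicate 1 (adjusted p = 0.287) and without background subtraction (0.0612). The pancreas markers were not called at day 8 (median -1.34, adjusted p = 0.0611; 0.00533 with the replicate number as a term), and the 2 arrays stood on opposite sides of 0: the median was 0.63 on replicate 1 and -3.50 on replicate 2.

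Over both days, 7797 genes passed, of which 3708 rose and 4089 fell (47.6% rose). With the replicate number as a term 11255 passed (49.4% rose). With the processed signals 6649 passed, and 6644 did with the authors' log10 values, and 55.7% of either rose. A change of at least 4-fold was far more often a fall (131 genes) than a rise (10 genes). Among those with a gene symbol Nat8 had the largest rise (3.74, SE 0.07, 13.4-fold, adjusted p = 0.000309), followed by Nat8f5 (3.47, SE 0.15), Gdpd3 (2.51), Phlda2 (2.44), Npb (2.23), Acot1 (2.19), Slc17a8 (2.16), Ces1e (2.06), Nox4 (1.83), Tmc7 (1.79), Colec10 (1.78) and Ntrk2 (1.73). Ifit1 had the largest fall (-4.75, SE 0.09, 27.0-fold, adjusted p = 0.000309), followed by Tgtp1 (-4.45), Saa1 (-4.39), Gbp6 (-4.32), Gbp3 (-4.31), Ifi44 (-4.18), Lcn2 (-4.15), Igtp (-4.07), Gbp8 (-4.00), Reg2 (-3.88), Saa3 (-3.85) and Cxcl9 (-3.84). Because the control pools recurred on both days, the 4 ratios are not fully independent and these p-values leave that out. Median centring left 269 genes (87 rose, 182 fell), and the count was 4742 without day 5 replicate 1, 3902 without day 5 replicate 2 and 4281 without day 8 replicate 2.

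**Figure D1:**
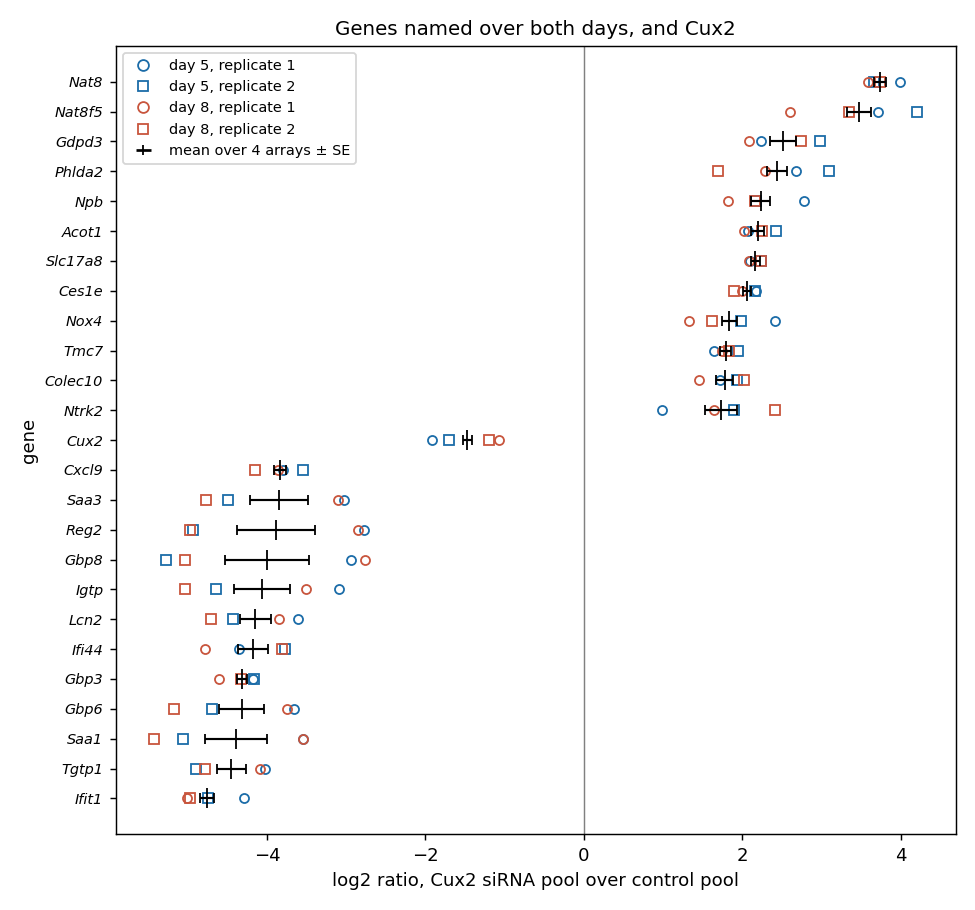
Log2 ratio of Cux2 siRNA over control (x axis) for the genes named over both days and for Cux2 (y axis); open symbols are single arrays by day and replicate, and the black marks give the mean over 4 arrays with its SE. Every array lies on the same side of 0 for each gene, from Nat8 (3.74) to Ifit1 (-4.75), and Cux2 is lower at day 5 than at day 8.

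The interferon response was the list with the largest share of members passing over both days. Of its 31 measured members 29 fell, none rose and 2 did not pass (30 fell adjusted over the list alone), with a median of -2.70 (camera adjusted p = 7.41e-22; adjusted p = 0.466 with an estimated correlation). Gbp3 fell by 4.31 (SE 0.06), Ifit1 by 4.75 (SE 0.09), Ifit3 by 3.04 (SE 0.05) and Ifit2 by 2.86 (SE 0.05). The transcription factor Irf7, the antigen-processing genes Psmb8 and Tap1 and the ubiquitin-like modifier Isg15 were among those that fell, and the interferon-signalling genes Stat2 and Irf9 did not pass. The acute phase list fell in 24 of 30 members, with 6 not passing (25 fell and 1 rose over the list alone), and had a median of -1.42 (adjusted p = 9.00e-12; adjusted p = 0.466 with an estimated correlation). A2m fell by 3.07 (SE 0.08), Orm3 fell by 3.26 (SE 0.15), Lcn2 by 4.15 (SE 0.20) and Orm2 by 3.68 (SE 0.19), and haptoglobin (Hp), haemopexin (Hpx) and both metallothioneins Mt1 and Mt2 fell, whereas the fibrinogen chains Fga, Fgb and Fgg, C-reactive protein (Crp) and hepcidin (Hamp) did not pass. Macrophage markers were lower beside both groups, with 15 of 18 falling (15 over the list alone), 3 not passing and a median of -0.69 (adjusted p = 3.37e-07; adjusted p = 0.517 with an estimated correlation). Aif1, a calcium-binding protein of macrophages, fell by 1.40 (SE 0.07), the scavenger receptors Msr1 and Marco by 0.59 (SE 0.05) and 2.84 (SE 0.26), and the lysosomal protein Laptm5 by 0.72 (SE 0.07). The Kupffer cell genes Clec4f, Cd5l and Timd4 fell, while Vsig4, Csf1r and Lyz2 did not pass. Neutrophil markers fell in 7 of 11 (7 over the list alone), with a median of -0.56 (adjusted p = 0.000744; adjusted p = 0.466 with an estimated correlation), which ranged from -1.50 to -0.15 under 4 other scalings. The chemokine receptor Cxcr2 fell by 0.62 (SE 0.05), myeloperoxidase (Mpo) by 0.56 (SE 0.05), and the calcium-binding pair S100a8 and S100a9 by 2.41 (SE 0.22) and 2.50 (SE 0.25). Lymphocyte markers were not called (1 rose, 7 fell and 8 did not pass of 16, the same over the list alone; adjusted p = 0.0679), although the killer-cell genes Klrk1 (-0.70), Nkg7 (-0.52), Gzma (-1.30) and Gzmb (-1.19) fell. That list was called without day 8 replicate 1 (adjusted p = 0.0279) and without day 8 replicate 2 (0.0393).

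Cell cycle genes fell in 26 of 29, with 3 not passing (27 over the list alone), and had a median of -0.89 (camera adjusted p = 1.37e-15; adjusted p = 0.466 with an estimated correlation), which ranged from -1.29 to -0.50 under 4 other scalings. Stmn1 fell by 1.32 (SE 0.06), Rrm2 by 1.52 (SE 0.07), Nusap1 by 1.31 (SE 0.06) and Cdc20 by 1.32 (SE 0.06). Replication genes (Mcm2 to Mcm7 and Pcna) and mitotic genes (Ccnb1, Cdk1, Top2a, Plk1) were both among those that fell, and the exceptions were Tyms, Cenpa and Ccne2. Stellate cell and fibroblast markers fell in 9 of 16, rose in 3 and did not pass in 4 (10 fell and 4 rose over the list alone), with a median of -0.49 (adjusted p = 0.0177; adjusted p = 0.616 with an estimated correlation). The actin-binding protein Tagln fell by 1.30 (SE 0.07), the metalloproteinase inhibitor Timp1 by 1.05 (SE 0.09) and the basement membrane collagen Col4a1 by 1.64 (SE 0.14), whereas Reln, a glycoprotein of quiescent stellate cells, rose by 0.91 (SE 0.09). The fibrillar collagens Col1a1, Col1a2 and Col3a1 fell, and Lrat, which stores vitamin A in stellate cells, rose. Macrophage and neutrophil markers were lower on the same arrays, as given above for the interferon group.

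Genes induced by the xenobiotic receptors CAR and PXR rose in 17 of 26 members, with no fall and 9 not passing (18 over the list alone), and had a median of 0.59 (camera adjusted p = 3.26e-07; adjusted p = 0.466 with an estimated correlation). The glutathione S-transferases Gstm1 and Gsta1 each rose by 1.02 (SE 0.05 and 0.06), the cytochrome P450 Cyp2c55 by 1.57 (SE 0.11) and Por, which passes electrons to cytochromes P450, by 0.65 (SE 0.06). The receptor genes themselves, Nr1i3 (CAR) and Nr1i2 (PXR), rose, and Cyp3a11 and Cyp2c29 did not pass. Heat shock genes rose in 11 of 15, fell in 1 and did not pass in 3 (12 rose and 1 fell over the list alone), with a median of 0.74 (adjusted p = 5.63e-06; adjusted p = 0.466 with an estimated correlation). The chaperones Hspa8 and Hsp90aa1 rose by 1.27 (SE 0.07) and 1.42 (SE 0.09). Hsph1, a nucleotide exchange factor for Hspa8, rose by 1.44 (SE 0.08) and the co-chaperone Chordc1 by 1.06 (SE 0.07). Serpinh1, a collagen chaperone, was the member that fell, and the inducible Hspa1a and Hspa1b did not pass. Cholesterol genes rose in 7 of 24, with 17 not passing (9 over the list alone), and had a median of 0.21 (adjusted p = 0.0177; adjusted p = 0.466 with an estimated correlation). Pmvk of the mevalonate pathway rose by 0.56 (SE 0.07) and lanosterol synthase (Lss) by 0.54 (SE 0.08). The cholesterol call was lost with the processed signals (adjusted p = 0.0595) and with the authors' values (0.0599).

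Several lists held strong changes in both directions and were not called over both days. In the circadian clock list 9 of 19 rose, 3 fell and 7 did not pass (9 and 3 over the list alone; camera adjusted p = 0.0677). The repressor Cry1 rose by 1.35 (SE 0.05), while Nr1d1, a repressor of the clock's activating arm, fell by 1.69 (SE 0.07) and its fellow output gene Dbp by 1.40 (SE 0.06). Arntl, Clock and Nfil3 rose and Nr1d2 fell. The clock list was called without day 5 replicate 1 (adjusted p = 0.0265) and without day 8 replicate 1 (0.0279), and also with the replicate number as a term (0.039). In the growth hormone and STAT5 list 8 of 21 rose, 7 fell and 6 did not pass (9 and 8 over the list alone; adjusted p = 0.941), and its median (0.06, -0.11 to 0.19 on leaving out each array) and mean (-0.17) differed in sign. The feedback inhibitors Socs2 and Socs3 fell by 1.05 (SE 0.05) and 1.19 (SE 0.11), the kinase Jak2 fell by 0.58 (SE 0.06), and the transcription factor Onecut1 rose by 0.43 (SE 0.06). Stress genes of the endoplasmic reticulum and of amino acid shortage rose in 4 of 22, fell in 8 and did not pass in 10 (5 and 9 over the list alone; adjusted p = 0.307). Trib3, a target of the amino acid response, fell by 2.42 (SE 0.06), and Asns and Chac1 of the same response fell, whereas the endoplasmic reticulum genes Manf, Hspa5 and Creld2 rose by 0.73 (SE 0.06), 0.60 (SE 0.05) and 0.64 (SE 0.06).

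Sex-biased genes, which the choice of Cux2 brings into question, moved in both directions. Of 37 measured female-biased genes 5 rose, 10 fell and 22 did not pass over both days (6 and 11 over the list alone; median -0.22, camera adjusted p = 0.189). Tox, a nuclear protein of the HMG box family, fell by 0.56 (SE 0.06), the cytochrome P450 Cyp2b9 by 0.63 (SE 0.07) and the organic anion transporter Slc22a26 by 0.59 (SE 0.08), while Ntrk2 rose by 1.73 (SE 0.20). Trim24, Bmper, Vldlr and Abcd2 fell and Tff3, Prlr and Slco1a4 rose. The female-biased list was called at day 5 (3 rose, 8 fell and 26 did not pass; 4 and 10 over the list alone; adjusted p = 0.0435, and adjusted p = 0.56 with an estimated correlation). That call was lost without day 5 replicate 1 (adjusted p = 0.276), without background subtraction (0.0938) and with a filter needing all 8 readings (0.0511). At day 8 it was not called (2 rose, 4 fell and 31 did not pass; 6 and 5 over the list alone; adjusted p = 0.687). Of 33 measured male-biased genes 11 rose, 3 fell and 19 did not pass over both days (11 and 4 over the list alone; median 0.14, -0.03 to 0.24 on leaving out each array, adjusted p = 0.245). Nat8 rose by 3.74 (SE 0.07) and Nox4 by 1.83 (SE 0.10), while Cyp2u1, a cytochrome P450, fell by 0.74 (SE 0.05) and the sulfotransferase Sult5a1 by 1.31 (SE 0.10). Ugt2b1, Cspg5, Cyp4a12b, Keg1 and Selenbp2 rose, and Mup1, Elovl3, Hsd3b5 and Cyp2d9 did not pass. The male-biased list was not called at day 5 (4 rose and 2 fell, 7 and 2 over the list alone; adjusted p = 0.229) or day 8 (6 rose and 3 fell, the same over the list alone; adjusted p = 0.256). It was called upwards at day 5 without day 5 replicate 2 (adjusted p = 0.0254), and without day 8 replicate 2 at day 8 (0.00484) and over both days (0.0354), a setting in which the female-biased list was also called over both days, downwards (0.0393).

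Metabolic and zonal lists of hepatocytes showed few changes as groups over both days. Genes of fatty acid and triglyceride synthesis rose in 7 of 20, with 13 not passing (8 over the list alone; camera adjusted p = 0.0711), among them Pnpla3 (1.73, SE 0.10), fatty acid synthase (Fasn, 0.72, SE 0.09) and the elongase Elovl6 (1.07, SE 0.14). That list was called without day 5 replicate 2 (adjusted p = 0.0237) and without day 8 replicate 2 (0.0263). Targets of PPAR alpha rose in 7 of 25 and fell in 2 (10 and 5 over the list alone; adjusted p = 0.218), with Acot1 (2.19), the peroxisomal thiolase Acaa1b (0.43) and the pyruvate dehydrogenase kinase Pdk4 (0.89) rising and the lipid droplet protein Plin2 (-0.46) falling. Bile acid genes rose in 1 of 19 and fell in 6 (3 and 7 over the list alone; adjusted p = 0.391), including the bile salt export pump Abcb11 (-1.07, SE 0.06) and Hsd3b7 of bile acid synthesis (-0.72, SE 0.06), and Cyp7a1, the rate-limiting enzyme, did not pass. Gluconeogenic and fasting genes rose in 1 of 13 and fell in 4 (2 and 4 over the list alone; adjusted p = 0.432): the serine dehydratase Sds fell by 0.71 (SE 0.05) and glucose-6-phosphatase (G6pc) rose by 0.96 (SE 0.13). Pericentral genes rose in 4 of 15 and fell in 4 (7 and 4 over the list alone; adjusted p = 0.519), with the dicarboxylate transporter Slc13a3 (-1.05), the Wnt-responsive receptor Lgr5 (-0.60) and the transcription factor Tbx3 (-0.60) falling and the glutamate transporter Slc1a2 (0.43) rising. Periportal genes rose in 2 of 12 and fell in 3 (the same over the list alone; adjusted p = 0.613), with the histidine ammonia-lyase Hal (-1.17, SE 0.09) falling and the urea cycle gene Asl (0.51, SE 0.06) rising.

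Among the remaining markers of other cell types, the exocrine pancreas list stood apart. Its 12 members had a median of -2.25 over both days (camera adjusted p = 0.0021; adjusted p = 0.616 with an estimated correlation), 4 of them fell and 8 did not pass (10 fell over the list alone). The 4 were the colipase Clps (-2.21, SE 0.59), the pancreatic lipase Pnlip (-3.47, SE 0.93), the trypsin gene Prss2 (-2.66, SE 0.72) and the carboxypeptidase Cpa1 (-2.62, SE 0.71). Each of these calls was lost without day 5 replicate 1 (adjusted p from 0.0881 to 0.113) and without day 5 replicate 2 (0.141 to 0.156). On leaving out each array Clps ranged from -3.12 to -1.30 and Pnlip from -4.84 to -2.10. Prss2 then ranged from -3.74 to -1.59 and Cpa1 from -3.68 to -1.56. The list's median was -2.69 and -3.55 on the day 5 arrays, 0.63 on day 8 replicate 1 and -3.50 on day 8 replicate 2. Endothelial markers (4 rose and 4 fell of 16, the same over the list alone; adjusted p = 0.673) and cholangiocyte markers (1 of 9 rose, 1 over the list alone; adjusted p = 0.397) were not called. Cdh5, the endothelial cadherin, fell by 0.36 (SE 0.05), and Sox9, the transcription factor of bile ducts, rose by 0.63 (SE 0.08). Erythroid markers rose in 2 of 9 (2 over the list alone; adjusted p = 0.397). The haemoglobin genes Hba-a1 and Hbb-bt did not pass over both days (-0.45 and -0.37), and at day 5 Hbb-bt fell by 1.07 (SE 0.20, adjusted p = 0.0318) while Hba-a1 was at -1.01 (adjusted p = 0.0525). Of 10 housekeeping genes 1 rose and 2 fell (the same over the list alone; adjusted p = 0.763). The 2 that fell were Gusb (-0.56) and Actb (-0.54), and the call of Actb was lost without day 5 replicate 2 (adjusted p = 0.0808) and without day 8 replicate 2 (0.0854).

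**Figure D2:**
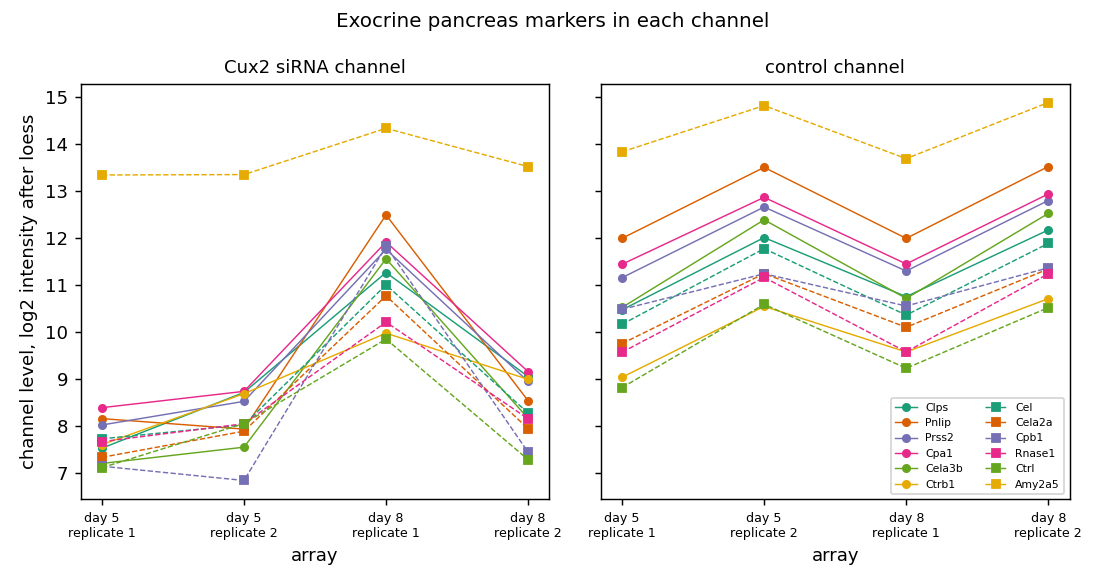
Level of each exocrine pancreas marker (y axis, log2 intensity after loess) in the Cux2 siRNA channel (left) and the control channel (right) of each array (x axis). Each line is 1 gene. The intensities were also scaled between arrays by Aquantile. In the left panel all 12 markers are higher on day 8 replicate 1 than on day 5 replicate 1, by a median of 3.48, and in the right panel the same arrays differ by a median of 0.166.

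**Figure D3:**
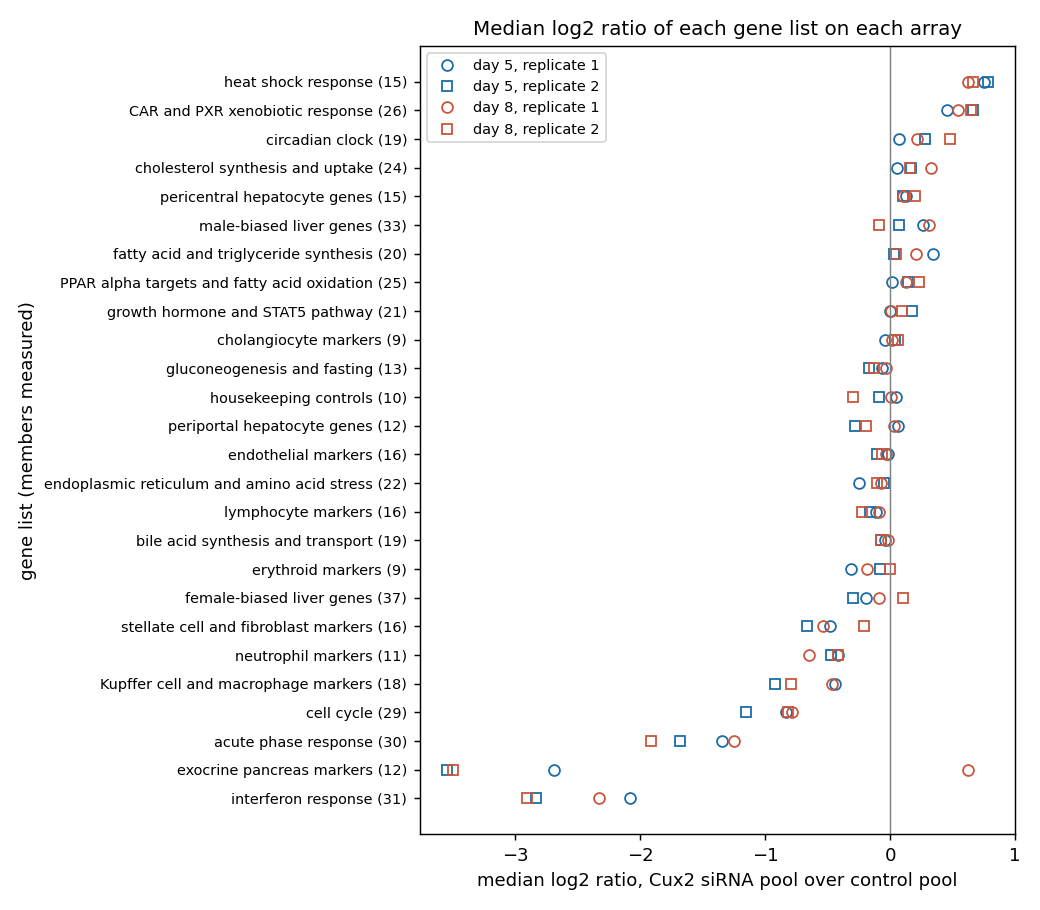
Median log2 ratio of Cux2 siRNA over control (x axis) for each gene list, with the number of members measured (y axis); each symbol is 1 array, by day and replicate. The interferon list lies lowest over both days (-2.70), and the pancreas list has 3 arrays far below 0 and 1 above it (0.63).

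No single gene differed between day 8 and day 5 (0 of 25091 by limma after adjustment, and 620 at an unadjusted p under 0.05), and no alternative setting gave any. Cux2 itself was less reduced at day 8, as stated above. Differences are given as values for genes with a symbol that differed at least 1.5-fold in the same direction in both replicates. The largest of these were higher at day 8 for Pnlip (2.46, SE 1.86), Reg1, another acinar cell product (2.05, SE 1.60), the mucin-like Dmbt1 (1.92, SE 0.79) and the primase subunit Prim2 (1.53, SE 0.27). They were lower for the desaturase Scd1 (-1.12, SE 0.78), Nat8f5 (-0.99, SE 0.30), profilin 2 (Pfn2, -0.95, SE 0.15) and Elovl6 (-0.93, SE 0.29). On leaving out each array the difference ranged from -0.28 to 5.20 for Pnlip, -0.11 to 4.21 for Reg1, 0.79 to 3.04 for Dmbt1, 1.17 to 1.89 for Prim2, -2.05 to -0.19 for Scd1, -1.36 to -0.62 for Nat8f5, -1.12 to -0.78 for Pfn2 and -1.28 to -0.58 for Elovl6. As groups, 7 of 26 lists differed by camera, 5 upwards and 2 downwards, and none with an estimated correlation (smallest adjusted p = 0.611 with an estimated correlation). Cell cycle genes were less reduced at day 8 (median difference 0.12, camera adjusted p = 6.69e-05; adjusted p = 0.611 with an estimated correlation), interferon genes more so (-0.15, adjusted p = 0.00118; adjusted p = 0.747 with an estimated correlation), and female-biased genes were higher (0.20, adjusted p = 0.00127; adjusted p = 0.611 with an estimated correlation). Each of these calls could be lost by leaving out 1 array. The difference then ranged from 0.05 to 0.25 for cell cycle, -0.27 to 0.07 for interferon and 0.13 to 0.25 for female-biased genes. The number of lists called was 12 with the replicate number as a term, 4 without day 5 replicate 1, 11 without day 5 replicate 2 and 12 without day 8 replicate 2.

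Day 5 and day 8 ratios were close across genes. Over 25091 genes, which are not independent replicates, Pearson's correlation was 0.919 and Spearman's 0.832, and day 8 ratios followed day 5 ratios with a slope of 0.876. Of the genes that rose, 1232 did so on both days against 116 for independent lists, and of those that fell 1728 against 190. No gene passed in opposite directions. Unchanged groups that shared the control pools gave a simulated correlation of 0.495 (20 runs) and a covariance of 0.00731. The observed covariance was 0.159, so that 0.152 remained after the simulated covariance was taken off. The simulation gave the control pools only independent noise per gene, sized from the spread between arrays. A difference common to both control pools is absent from it, so the remainder may still hold a share from the controls. With 2 control pools no split of the controls could leave 2 pools on each side. Part of the excess over the independent overlap may come from the shared controls. Both days also used the same estimate of spread for each gene, which by itself makes their calls coincide more often than independent lists would. Between single arrays the correlation was 0.84 and 0.883 for the same replicate number on different days and 0.791 and 0.712 for the same day. It was 0.738 and 0.753 for pairs that differed in both day and dye orientation.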

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

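All tests of explanations in this part were chosen only after the results had been seen; the camera tests of the difference between the days had been fixed in the design. The 7 gene lists given here came up because camera found their day 8 ratios to differ from their day 5 ratios, and in each the call was lost with an estimated correlation. Exocrine pancreas markers had medians of -3.10 at day 5 and -1.34 at day 8 (median difference 1.71, camera adjusted p = 0.000758; adjusted p = 0.747 with an estimated correlation). Cell cycle genes went from -1.0035 to -0.7983 (median difference 0.12, adjusted p = 6.69e-05; adjusted p = 0.611 with an estimated correlation) and interferon genes from -2.57 to -2.83 (-0.15, adjusted p = 0.00118; adjusted p = 0.747 with an estimated correlation). Female-biased genes went from -0.26 to -0.16 (0.20, adjusted p = 0.00127; adjusted p = 0.611 with an estimated correlation) and gluconeogenic genes from -0.07 to -0.02 (0.16, adjusted p = 0.00282; adjusted p = 0.611 with an estimated correlation). Heat shock genes went from 0.79 to 0.69 (-0.11, adjusted p = 0.017; adjusted p = 0.611 with an estimated correlation) and cholesterol genes from 0.14 to 0.24 (0.10, adjusted p = 0.0347; adjusted p = 0.611 with an estimated correlation). Each of the 7 calls could be lost by leaving out 1 array. The difference then ranged from -0.28 to 3.68 for pancreas, 0.05 to 0.25 for cell cycle and -0.27 to 0.07 for interferon genes. It ranged from 0.13 to 0.25 for female-biased and 0.13 to 0.25 for gluconeogenic genes. For heat shock genes it was -0.12 to -0.10 and for cholesterol genes 0.07 to 0.15. With 2 arrays per day no array could be tested as standing apart from its group.

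The joint fall of interferon, acute phase and cell cycle genes is a pattern that a reaction of the control livers, a loss of macrophages or the loss of Cux2 could each leave. The interferon median lay 2.01 below that of the macrophage markers (difference -2.01, 31 against 18 genes, 2-sided permutation p = 0.00094, adjusted p = 0.00282). Interferon genes thus fell further than these markers. The permutation treats genes as independent, although members of each list moved together (estimated correlations 0.244 and 0.504). It does not measure the spread between pools, and the markers' median does not bound a loss of macrophages. Fewer macrophages as the whole cause therefore stay open for interferon genes. That cause stays open too for acute phase genes (difference -0.73, permutation p = 0.0413, adjusted p = 0.062) and cell cycle genes (-0.19, p = 0.139, adjusted p = 0.139). A fall in proportion to the loss of Cux2 RNA stays open. The Cux2 log2 ratio at day 8 was 0.628 of that at day 5 (SE 0.0564). For interferon and acute phase genes the value was 1.06 (SE 0.0575) and 1.1 (SE 0.0615). Their mean excess over Cux2 was 0.426 and 0.454 across the 2 replicate numbers (SE between them 0.0585 and 0.077). On the mean of each day these falls were thus no smaller at day 8. However, the SEs of 1.06 and 1.1 come partly from resampling genes that move together. The mean excess rests on 2 pairs of arrays, and a single probe measured Cux2. A fall in proportion is therefore not excluded, and a response that saturates at the lesser depletion stays open too. For cell cycle genes the ratio was 0.861 (SE 0.0596), and within replicate 2 it was 0.793 against 0.705 for Cux2. Their mean excess over both numbers was 0.235 (SE between them 0.148). A reaction to siRNA in the control mice, collected at another time after treatment, cannot be told apart from an effect of Cux2, because the labels give the controls no day, and the small changes of cell cycle (0.1151) and interferon genes (-0.1454) between the days decide nothing; the effect of Cux2 depletion itself stays open, untested.

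The shifted clock genes may reflect pools collected at different times of day. Genes that peak with Arntl lay 1.68 above genes that peak with Nr1d1 (5 against 7 genes, 2-sided exact permutation p = 0.00253 over 792 arrangements), but the phases were assigned after the values had been seen, so this neither argues for nor against it. A shift in proportion to the loss of Cux2 RNA stays open as well. The slope of day 8 on day 5 ratios of the 19 clock genes was 0.87 (SE 0.0824) against 0.628 for Cux2. Within replicate 1 it was 0.891 against 0.559 (difference 0.332, SE 0.101) and within replicate 2 0.853 against 0.705 (difference 0.148, SE 0.104). These SEs come from resampled genes and the spread of Cux2 over all arrays, as each day has 1 array there. The mean difference was 0.24 (SE between the 2 replicate numbers 0.092). An effect of Cux2 on the clock that does not scale with its RNA was not tested, and the labels give no time of day.

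The pancreas markers are lower in the treated pools on 3 of the 4 arrays and higher on day 8 replicate 1, which could come from pancreas RNA carried into both control pools and into that 1 treated pool. In the Cux2 siRNA channel all 12 markers were higher on day 8 replicate 1 than on day 5 replicate 1, by a median of 3.48 (SD 1.03), against 0.166 in the control channel of the same arrays and 0.322 in the treated channel of the replicate 2 arrays. Of the 12, Amy2a5 stayed between 13.3 and 14.9 in every channel (log2 intensity after loess and Aquantile scaling). Pnlip instead stood at 12.5 in the treated channel of day 8 replicate 1 and at 8.15, 7.93 and 8.53 in the other treated channels. The account stays open, as it was drawn from these same values, and Reg2, an acinar product outside the list, did not rise there: its log2 ratio was -2.85 on day 8 replicate 1 and -2.77 on day 5 replicate 1, while Reg1 went from -3.38 to -0.37. The interferon median of that array was -2.33, within the range of the other arrays, which argues against a fault across the whole array. A fault limited to the pancreas spots would not show in that median, and no biological explanation was tested.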

How the results depend on the processing

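All alternatives in this part had been listed before the data were examined; only the split of their effects into those told at length and those counted was chosen after. The fall of Cux2 kept its direction under every alternative for which its value was taken. None was taken for the setting with no filter on dim probes. Leave-one-out values were -1.91 to -1.70 at day 5 and -1.20 to -1.07 at day 8. Its call was lost with median centring (-1.82, limma adjusted p = 0.129, at day 5 and -1.13, adjusted p = 0.277, at day 8). At day 8 it was also lost without day 8 replicate 2 (-1.07). Counts of genes on each day and over both days moved widely between settings. At day 5 (4216 genes) they were 5 with median centring, 2004 with processed signals, 1994 with the authors' log10 table, 8238 with the replicate block, 6612 at an adjusted p of 0.1, 2021 with a 1.5-fold minimum and 246 to 3560 on leaving out each array. At day 8 (3595 genes) they were 3 with median centring, 2108 without background subtraction, 1475 with processed signals, 1463 with the authors' table, 7453 with the replicate block, 5934 at an adjusted p of 0.1, 1799 with a 1.5-fold minimum and 137 to 2497 on leaving out each array. Over both days (7797 genes) they were 269 with median centring, 11255 with the replicate block, 2078 with a 1.5-fold minimum and 3902 to 5463 on leaving out each array. A wider threshold or a fold minimum moves a count by its construction, and leaving out an array removes a residual degree of freedom; for the other settings the cause was not tested. Other scalings left the median of all genes within 0.05 of 0. Of the 24 genes named per day, median centring ended 22 calls at day 5 and 23 at day 8, no background subtraction ended 6 and 6, and processed signals 2 and 2; over both days median centring ended 79 of 114 and the replicate block none. Apart from these counts, 9 list calls (8 gained, with lymphocyte markers at day 5 lost at -0.17, adjusted p = 0.0599, and gains for pancreas and PPAR alpha at day 8, clock over both days and acute phase, clock, erythroid, periportal and PPAR alpha in the difference) and 3 gene calls gained over both days (Epcam 0.15, Slc4a1 -0.18 and Hprt 0.22), the replicate block changed no other call. A setting that leaves a day with 1 array borrows the spread of the other day.

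The number of lists called went to 0 in each contrast with an estimated correlation (smallest adjusted p 0.522 at day 5, 0.459 at day 8, 0.466 over both days and 0.611 for the difference). By construction that test refers to the 2 residual degrees of freedom, which alone makes a call over 26 lists hard to reach. For some lists the estimated correlation was also far above the preset 0.01, up to 0.993 for pancreas markers. For the difference between days 7 lists became 12 with the replicate block and 4 to 12 on leaving out each array; eBayes with trend and robust estimation ended 2 of the 7 calls, and median centring, no background subtraction, processed signals and the authors' log10 values ended 1 each. Some directions turned on leaving out each array, and the cause was not tested: the pancreas list ranged from -3.50 to 0.63 at day 8, and in the difference between days from -0.28 to 3.68, the acute phase list from -0.61 to 0.28, the interferon list from -0.27 to 0.07, the macrophage list from -0.22 to 0.33, the male-biased list from -0.14 to 0.12, Pnlip from -0.28 to 5.20 and Reg1 from -0.11 to 4.21. Lists called under neither of 2 settings turned direction in 53 of 1456 pairs of list and setting. The correlation of day 5 with day 8 (0.919) was 0.839 with processed signals, 0.839 with the authors' table and 0.830 to 0.882 on leaving out each array. Signal limits the dim genes: spot medians lay at 381.5 to 471.5 over backgrounds of 306 to 342.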

Other observations

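The gene families and the channel levels in this part were chosen only after the results had been seen. Major histocompatibility genes and a minority of proteasome subunits were lower. Of 21 major histocompatibility genes measured, 14 fell, none rose and 7 did not pass over both days, with a median of -0.85 (camera adjusted p = 7.95e-06; adjusted p = 0.473 with an estimated correlation). Of 43 proteasome subunits 15 fell, 1 rose and 27 did not pass (median -0.15, adjusted p = 3.4e-05; adjusted p = 0.298 with an estimated correlation). The largest falls there were in the subunits that interferon induces to make the immunoproteasome, Psmb9 (-2.26), Psmb8 (-1.80, itself in the interferon list) and Psmb10 (-1.30), and in the activator subunits Psme2 (-0.97) and Psme1 (-0.79). In the Serpina3 group of protease inhibitors 3 of 5 fell (median -0.53, adjusted p = 0.0087; adjusted p = 0.473 with an estimated correlation), with array medians of -0.53 and -0.91 at day 5 and of -0.07 and -1.16 at day 8. Macrophage markers fell on the same arrays (median -0.69).

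Carboxylesterases and glutathione S-transferases moved up. Of 14 carboxylesterases 9 rose, none fell and 5 did not pass (median 0.77, camera adjusted p = 3.4e-05; adjusted p = 0.273 with an estimated correlation), led by Ces1e (2.06), Ces2b (1.68), Ces2c (1.64) and Ces1g (1.35). Of 18 glutathione S-transferases, some of which are also in the xenobiotic list, 10 rose and 1 fell (median 0.31, adjusted p = 0.000181; adjusted p = 0.273 with an estimated correlation). Cytosolic ribosomal protein genes had a small upward median of 0.14, with 11 of 76 rising and 2 falling (adjusted p = 0.00579; adjusted p = 0.7 with an estimated correlation). That shift lay in 1 dye orientation, with array medians of 0.39 and 0.14 in replicate 1 of day 5 and day 8 against 0.0017 and 0.0022 in replicate 2, and it was not called at day 8 (adjusted p = 0.192). Not called were the collagens (3 rose and 11 fell of 35; adjusted p = 0.0522), the UDP-glucuronosyltransferases (4 rose of 14; adjusted p = 0.44), the Slc22 transporters (6 rose and 3 fell of 18; adjusted p = 0.399), the aminoacyl-tRNA synthetases (7 rose and 4 fell of 19; adjusted p = 0.28) and the complex I subunits (2 rose of 35; adjusted p = 0.99). The medians of the called families kept their sign under 4 scaling alternatives.

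Replicate number and dye orientation coincide, and the major urinary protein gene Mup1, chosen after its values were seen, was at 0.67 and 1.36 in the replicate 1 arrays of day 5 and day 8 and at -0.89 and -1.27 in the replicate 2 arrays.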
